A study of Mus musculus with 6 samples.

How the data were processed

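Bulk RNA sequencing was done on LSK cells (lineage-negative, Sca-1-positive, c-Kit-positive cells) sorted from the bone marrow of C57BL/6J mice at 3 months of age. The 6 libraries comprise 3 wild-type and 3 Etv6 R355X/+ libraries, grouped by their titles. The genotype field of the labels writes the mutant as Etv6+/-, and the series text names the R355X allele. Per the labels' protocols, c-Kit-positive cells were enriched on magnetic beads before sorting, total RNA was amplified with a single-primer isothermal kit, the cDNA was sheared, and libraries were built from it. This amplification does not select polyadenylated RNA, so ribosomal RNA and non-polyadenylated transcripts were counted too, and it does not mark the strand.

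The deposited table holds expected counts per gene and library, made by the authors and not scaled for library size. Per the submitters' processing notes, Trim Galore 0.60, STAR 2.7 and RSEM 1.31 were used with build mm10. The annotation release and read filters are not given in the sources used here. Expected counts share out reads that map to several genes, so values of closely related genes depend on that split. This concerns the stefin A, beta-globin and Klrb1 families and the immunoglobulin segments. Genes that overlap on opposite strands, Etv6 and its antisense neighbours among them, also share reads without strand information. The table lists 55573 genes, of which 55394 matched the GENCODE annotation used here for positions, transcript lengths and GC content by identifier without version. A further 92 spike-in rows were listed at 0 in every library and left out. Totals were 60.8, 47.9 and 48.4 M expected counts in wild-type replicates 1, 2 and 3, and 92.2, 51.1 and 45.2 M in mutant replicates 1, 2 and 3.

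Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr, which kept 20646, and libraries were scaled by TMM. Genotypes were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors were taken from the fold change and its F statistic. CPM values use the TMM-scaled library size and are given as mean ± SD with n = 3 per genotype. Gene lists written before the data were examined were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01. The 34 lists with at least 5 tested members were adjusted together. The same test with an estimated correlation, and fry, were alternatives. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members' p-values of the same edgeR fit. Etv6 was also compared with an exact two-sided permutation test of log2 CPM.

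The named genes follow a rule fixed before the data were examined. It takes Etv6, and the 12 largest rises and 12 largest falls among genes past the threshold whose genotypes do not overlap and whose higher genotype averages at least 1 CPM. Symbols of the Gm and Rik series and pseudogenes are passed over. It also takes up to 4 members of each list with the smallest adjusted p, the sorting markers Ly6a and Kit, and sex-linked genes. A few genes that the rule takes are not reported here. Genes outside the rule are said to be so where they are named.

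Every pair of replicates of a genotype differed by more than sampling noise, with a chi-square per gene between 11.3 and 48.6, so no library was taken for a repeat of another. The labels do not say that the replicates come from separate animals, so p-values measure the spread between these samples, which may be technical. The scripts were tested on data simulated from the real means, library sizes and dispersions of the comparison of Etv6 R355X/+ with wild type, with 200 changed genes in each of 5 draws and at least 20306 genes tested per draw. At a fold change of 1.5, 32.7% of changed genes were called in the right direction, at 2 62.7% and at 4 84.0%. False calls made up 11.6% of all calls in these draws, above the nominal level. A list of 40 genes shifted by 1.2-fold had an unadjusted camera p under 0.05 in 5 of 5 draws, and a list left alone in 1 of 5. Genes were drawn independently of each other. These draws therefore do not test camera on lists whose members vary together, such as ribosomal proteins (estimated correlation 0.855).

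The alternatives tried were DESeq2 1.42.0, limma-voom, robust estimation, RLE size factors, library size alone, other count filters, unrounded counts, a test against a fold of 1.2, the replicate number as a block, leaving out mitochondrial genes, and leaving out each library in turn. After the data were seen, a trend with transcript length and GC content, leaving out mutant replicate 1 and wild-type replicate 3 together, and leaving out ribosomal RNA genes were added. Lengths and GC content were found for 99.9% of the tested genes.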

Results

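LSK cells are a bone marrow fraction enriched for hematopoietic stem cells and multipotent progenitors. They were profiled by RNA sequencing in 3 wild-type libraries and 3 libraries from mice heterozygous for the R355X allele of Etv6, which encodes a transcriptional repressor of the ETS family. The series title sets the question as the control of inflammatory genes by ETV6. Depth ranged from 45.2 M to 92.2 M expected counts per library, with mutant replicate 1 the deepest. That library also had the highest share of nuclear-encoded ribosomal RNA, 8.61% against 6.30% to 7.19% in the others (mitochondrial ribosomal RNA took 18.4% to 19.8%, most in mutant replicate 3), and of the ribosomal transcript AY036118, 1.26% against 0.247% to 0.431%, a transcript singled out after its values were seen.

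Etv6 itself, on chromosome 6 from 134035700 to 134270158 in mm10 (ENSMUSG00000030199.16), measured 424 ± 27.2 CPM in wild type and 344 ± 40.5 CPM in the mutant (SD, n = 3). The mutant level was 81.0% of wild type, with an approximate 95% interval from 72.1% to 91.1% (normal approximation to the fit). The log2 fold change of -0.30 (SE 0.086) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (unadjusted p = 0.00506, adjusted p = 0.245). All 3 mutant values lay below all 3 wild-type values, which gives an exact two-sided permutation p of 0.1, the smallest possible with 3 against 3. The 5 annotated genes that overlap Etv6 had log2 fold changes from 0.091 to 0.50. Some of them lie on the strand of Etv6 and others on the opposite strand. Overlapping genes can share reads, and with unstranded counts this holds for opposite strands too. Part of the Etv6 difference may therefore lie in that split, which was not tested.

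A small set of genes passed the adjusted threshold between mutant and wild-type LSK libraries. Stfa1, a stefin family inhibitor of cysteine proteases, rose from 0.0805 ± 0.0535 to 3.03 ± 0.786 CPM, and its family member Cstdc5 from 0.126 ± 0.0782 to 2.48 ± 0.482 CPM. Fcer1a, the alpha chain of the high-affinity IgE receptor, rose from 0.499 ± 0.0776 to 2.49 ± 0.380 CPM, and the adult beta-globin gene Hbb-bt from 18.1 ± 2.75 to 78.5 ± 22.7 CPM. Among the falls, Apob, the apolipoprotein of very-low-density particles, went from 5.11 ± 0.379 to 1.09 ± 0.488 CPM, and the nuclear receptor gene Hnf4a from 26.2 ± 7.06 to 10.5 ± 2.51 CPM. Of 20646 genes tested, 55 passed, 39 higher and 16 lower in the mutant, and 32 of them differed by more than 2-fold. An unadjusted p under 0.05 in the same edgeR test was found for 2194 genes. The simulated draws recovered 32.7% of changes of 1.5-fold, so genes that did not pass are not shown to be unchanged.

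The other named rises were the kappa variable segment Igkv3-4 (log2 fold change 6.48, SE 0.66), Grrp1 (3.26, SE 0.54) and Pkd1l3 (2.37, SE 0.22). They also took in the natural killer receptor gene Klrb1c (1.82, SE 0.25) and the complement gene C4b (1.72, SE 0.26). Slc27a2, which encodes an acyl-CoA synthetase for very long fatty acids (1.65, SE 0.19), Cyyr1 (1.58, SE 0.21) and Pik3r6, a regulatory subunit of phosphoinositide kinase (1.56, SE 0.22), completed them. Igkv4-72 (-2.46, SE 0.38), Plxdc2 (-1.24, SE 0.17) and the myosin gene Myo6 (-1.18, SE 0.16) fell, as did the IgA constant region Igha (-1.08, SE 0.18). Serpinf1, which encodes a secreted serpin (-0.98, SE 0.10), Lilr4b (-0.80, SE 0.12) and the adenylate kinase gene Ak4 (-0.76, SE 0.13) were also lower. Dock1, an exchange factor for Rac (-0.67, SE 0.10), Igkv1-117 (-0.67, SE 0.10) and Ndrg1 (-0.57, SE 0.096) made up the rest. Igkv3-4, Igkv4-72, Igkv1-117 and Igha are immunoglobulin genes, and the kappa constant region Igkc measured 1713 ± 452 and 1834 ± 123 CPM in wild type and mutant. Their changes may lie in carried-over B-lineage cells rather than LSK cells, which was not tested.

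The naming rule took only genes whose genotypes do not overlap. Adjusted p of the 24 named genes ran from 0.00213 to 0.0441 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 55 calls were non-overlapping, against 16.3% of all tested genes and the 10% that chance gives for 3 against 3. Genes with so small a p in 3 against 3 seldom overlap, so this is no separate support for the calls. The count fell to 23, 16, 26 and 18 genes without wild-type replicate 1, wild-type replicate 2, mutant replicate 1 and mutant replicate 2. It was 56 without mutant replicate 1 and wild-type replicate 3 together, a setting chosen after seeing the data, and 36 genes were shared with the 55. Igkv3-4, Stfa1, Cstdc5, Pkd1l3, Fcer1a, Hbb-bt, Slc27a2 and Serpinf1, 8 of the 24, kept the call whichever library was left out.

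**Figure D1:**
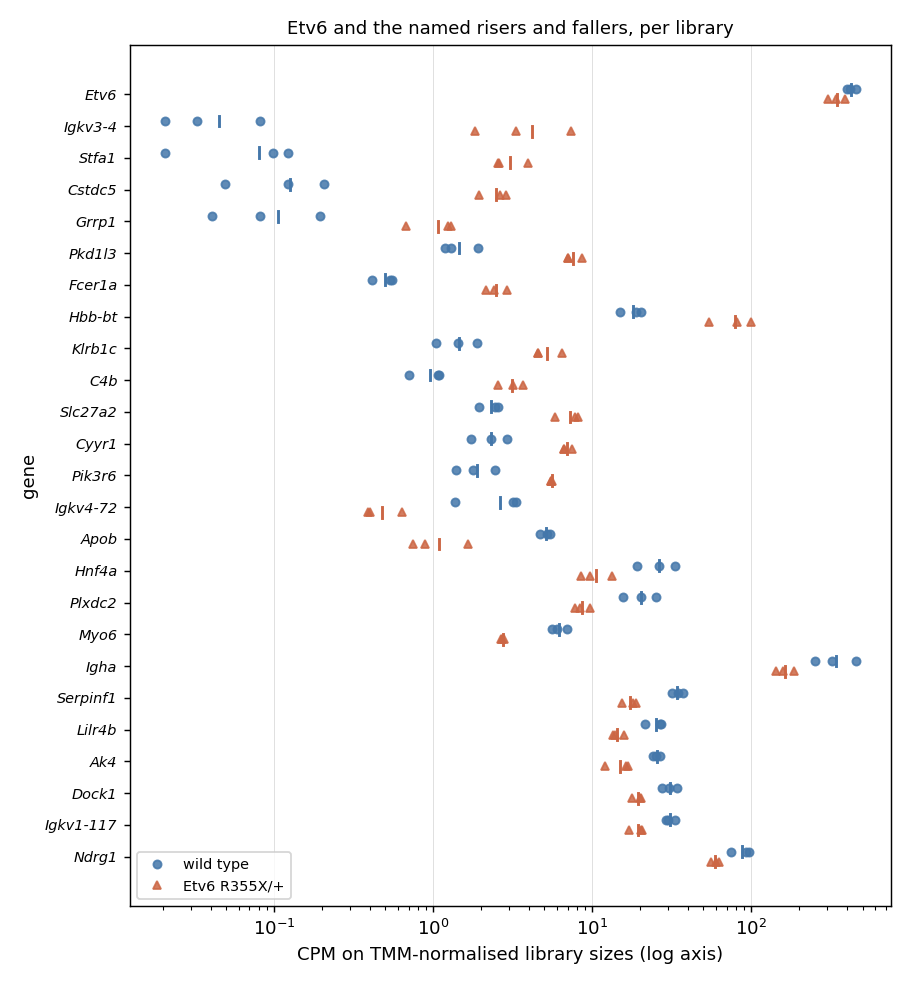
CPM on TMM-scaled libraries (log axis) of Etv6 and the 24 named genes; circles are the 3 wild-type libraries, triangles the 3 Etv6 R355X/+ libraries, and vertical ticks the genotype means. Stfa1 lies near 0.0805 CPM in wild type and 3.03 CPM in the mutant. The rule for the 24 genes took only genes whose genotypes do not overlap.

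Some inflammatory gene lists fixed beforehand passed camera at the preset correlation and others did not. Of the 34 lists of all kinds, 16 passed that test and 0 passed with an estimated correlation. Splits of the 6 libraries that mixed the genotypes passed 10 to 22 lists. Partners and GTPases induced by interferon gamma rose with a median log2 fold change of 0.28, and 26 of 30 members were above 0 (camera adjusted p = 8.47e-07; adjusted p = 0.406 with an estimated correlation). None of these 30 passed over all genes in edgeR's quasi-likelihood test, where 12 had an unadjusted p under 0.05. Adjusted over the list alone, 6 passed, all higher, and DESeq2 called 5 and limma-voom 0. Irf1, a transcription factor of the interferon response, measured 39.4 ± 2.57 CPM in wild type and 49.1 ± 1.45 CPM in the mutant. The GTPase gene Ifi47 measured 100.0 ± 3.36 and 122 ± 12.2 CPM. The median was 0.13 without mutant replicate 2 (adjusted p = 0.00130).

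The list of interferon-stimulated genes did not pass, with a median log2 fold change of 0.014 over 59 members (camera p = 0.382, adjusted p = 0.464; adjusted p = 0.883 with an estimated correlation). The difference of its library medians was 0.0099 with an SE of 0.062. No member passed edgeR's quasi-likelihood test over all genes and 0 adjusted over the list alone, while 9 had an unadjusted p under 0.05 (7 higher, 2 lower), DESeq2 called 1 and limma-voom 0. Oas1g measured 10.2 ± 0.513 CPM in wild type and 13.6 ± 0.581 CPM in the mutant, and Pml 89.8 ± 5.64 and 78.9 ± 4.29 CPM. Camera passed without wild-type replicate 1 (median 0.062, adjusted p = 0.0372) and without mutant replicate 2 (median 0.035, adjusted p = 0.0446). Medians were -0.021, -0.025 and 0.0049 without wild-type replicate 3, mutant replicate 1 and mutant replicate 3. It passed in the other direction without mutant replicate 1 and wild-type replicate 3 together (median -0.051, adjusted p = 0.0352).

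TNF and NF-kappaB target genes did not pass either, at a median of 0.063 over 60 members (camera p = 0.163, adjusted p = 0.231; adjusted p = 0.715 with an estimated correlation). Of the 60, 0 passed edgeR's quasi-likelihood test over all genes and 0 adjusted over the list alone, while 7 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. The activation marker Cd69 measured 29.9 ± 5.44 and 41.6 ± 1.92 CPM in wild type and mutant, and the inhibitor Nfkbia 9.95 ± 0.128 and 12.8 ± 0.643 CPM. The list passed without wild-type replicate 1 (median 0.092, adjusted p = 0.0372), and its median was 0.038 without wild-type replicate 3.

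Antigen presentation and sensing lists passed camera as higher at the preset correlation. MHC class II genes were above 0 in 11 of 11 members (median 0.32, camera adjusted p = 1.53e-05; adjusted p = 0.406 with an estimated correlation), with H2-Ab1 at 61.0 ± 13.3 and 85.9 ± 27.4 CPM in wild type and mutant. Class II genes are also markers of dendritic cells, macrophages and B cells, whose lists were higher too (medians 0.52 and 0.42). MHC class I genes were above 0 in 17 of 23 (median 0.16, camera adjusted p = 1.93e-05; adjusted p = 0.406 with an estimated correlation), with B2m at 1905 ± 62.5 and 2198 ± 111 CPM. In both MHC lists 0 members passed edgeR's quasi-likelihood test, over all genes or adjusted over the list alone; 4 class II and 11 class I genes had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Pattern recognition and inflammasome genes were above 0 in 27 of 41 (median 0.11, camera adjusted p = 0.00658; adjusted p = 0.396 with an estimated correlation). Of these 41, 0 passed over all genes in edgeR's test, 6 had an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 0. Adjusted over the list alone, 2 passed, namely the receptor genes Naip6, at 14.0 ± 1.86 and 20.5 ± 2.57 CPM, and Tlr1, at 3.03 ± 0.935 and 5.76 ± 0.838 CPM. The medians of MHC class II and class I were 0.53 and 0.25 without mutant replicate 3. Their lowest values with a single library left out were 0.23 for class II (mutant replicate 2) and 0.13 for class I (mutant replicate 1). The pattern recognition median was 0.063 without mutant replicate 1. Without mutant replicate 1 and wild-type replicate 3 together its adjusted p was 0.0548, and the class I median was 0.086.

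Lists of several blood lineages passed camera as higher in the mutant at the preset correlation. Mast cell, basophil and eosinophil genes were above 0 in 18 of 18 members (median 0.59, camera adjusted p = 5.31e-09; adjusted p = 0.396 with an estimated correlation). Of these, Fcer1a passed over all genes and 8 passed adjusted over the list alone. The eosinophil granule gene Prg2 measured 10.9 ± 1.13 and 16.7 ± 2.39 CPM in wild type and mutant, and the basophil protease gene Prss34 5.46 ± 1.29 and 11.2 ± 5.25 CPM. B cell genes were above 0 in 20 of 23 (median 0.42, camera adjusted p = 1.01e-08; adjusted p = 0.406 with an estimated correlation); 1 passed over all genes and 11 adjusted over the list alone. The lambda constant region Iglc1 rose from 24.5 ± 1.80 to 54.3 ± 9.17 CPM, and Vpreb1, a surrogate light chain gene, measured 6.42 ± 1.01 and 16.1 ± 8.03 CPM. The B cell median was 0.28 without mutant replicate 1.

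Multipotent progenitor and lymphoid-priming genes were above 0 in 29 of 35 (median 0.24, camera adjusted p = 2.23e-07; adjusted p = 0.406 with an estimated correlation). Over all genes 1 passed, the calponin gene Cnn3, and adjusted over the list alone 12 were higher and 2 lower. The recombinase genes Rag1 and Rag2 measured 14.9 ± 0.720 and 16.9 ± 0.523 CPM in wild type and 31.1 ± 10.7 and 32.7 ± 12.1 CPM in the mutant. Macrophage and dendritic cell genes were above 0 in 20 of 24 (median 0.52, camera adjusted p = 3.00e-07; adjusted p = 0.406 with an estimated correlation). Over all genes 0 of these passed edgeR's quasi-likelihood test and 15 had an unadjusted p under 0.05; adjusted over the list alone 13 were higher and 1 lower, and DESeq2 called 7 and limma-voom 0. The complement gene C1qa measured 2.55 ± 0.166 and 4.80 ± 1.35 CPM, and Cd68 13.6 ± 1.48 and 19.4 ± 2.20 CPM. The macrophage median was 0.31 without mutant replicate 1. Without mutant replicate 1 and wild-type replicate 3 together it was 0.25, and the lymphoid-priming median 0.069.

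Myeloid progenitor genes were lower, with 23 of 31 members below 0 (median -0.16, camera adjusted p = 0.000451; adjusted p = 0.684 with an estimated correlation). In edgeR's quasi-likelihood test 0 passed over all genes or adjusted over the list alone and 9 had an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 0. Ly6c2 measured 137 ± 39.0 and 95.2 ± 15.6 CPM in wild type and mutant. The call ended without wild-type replicate 3 (median -0.045, adjusted p = 0.403) and without mutant replicate 3 (median -0.15, adjusted p = 0.0682). It also ended without mutant replicate 1 and wild-type replicate 3 together (median -0.051, adjusted p = 0.188). Medians were -0.28, -0.31 and -0.25 without wild-type replicate 1, wild-type replicate 2 and mutant replicate 2.

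Long-term stem cell genes went both ways and did not pass as a list (median -0.087 over 43 members, camera adjusted p = 0.209; adjusted p = 0.820 with an estimated correlation). Fgd5, a marker of stem cells and endothelium, rose from 9.82 ± 1.12 to 24.5 ± 2.63 CPM and passed over all genes. Adjusted over the list alone, 2 members were higher and 3 lower, and fry's mixed test, which allows both directions, gave its smallest adjusted p here (0.00198). Procr, which encodes the endothelial protein C receptor, measured 21.9 ± 2.01 and 16.3 ± 0.796 CPM in wild type and mutant. The list was lower without wild-type replicate 3 (median -0.16, adjusted p = 0.00148) and without mutant replicate 1 and wild-type replicate 3 together (median -0.041, adjusted p = 0.0186). Medians were -0.036 and -0.058 without wild-type replicate 1 and wild-type replicate 2, where it did not pass.

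Both adult beta-globin genes passed over all genes and adjusted over the list alone, with Hbb-bs at 29.5 ± 4.65 and 70.4 ± 21.5 CPM in wild type and mutant, but erythroid genes did not pass as a list (median -0.19, camera adjusted p = 0.702; adjusted p = 0.921 with an estimated correlation). The erythroid list was higher without wild-type replicate 3 (median 0.25, adjusted p = 0.00248) and lower without wild-type replicate 2 (median -0.35, adjusted p = 0.0425). Erythroid medians were -0.37, -0.33 and -0.0098 without wild-type replicate 1, mutant replicate 1 and mutant replicate 3. T and natural killer cell genes did not pass (median 0.45, camera adjusted p = 0.0536; adjusted p = 0.715 with an estimated correlation). Klrb1c passed over all genes, and adjusted over the list alone 1 gene was higher and 1 lower. The T and natural killer list passed without wild-type replicate 1, mutant replicate 2 and mutant replicate 3 (adjusted p = 0.00222, 0.0357 and 0.00181). Its adjusted p reached 0.754 without mutant replicate 1, where the median was 0.14, and the median was 0.27 without wild-type replicate 2. The list also passed with library size alone (adjusted p = 0.0106), with RLE factors (adjusted p = 0.0463) and with the replicate number as a block.

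**Figure D2:**
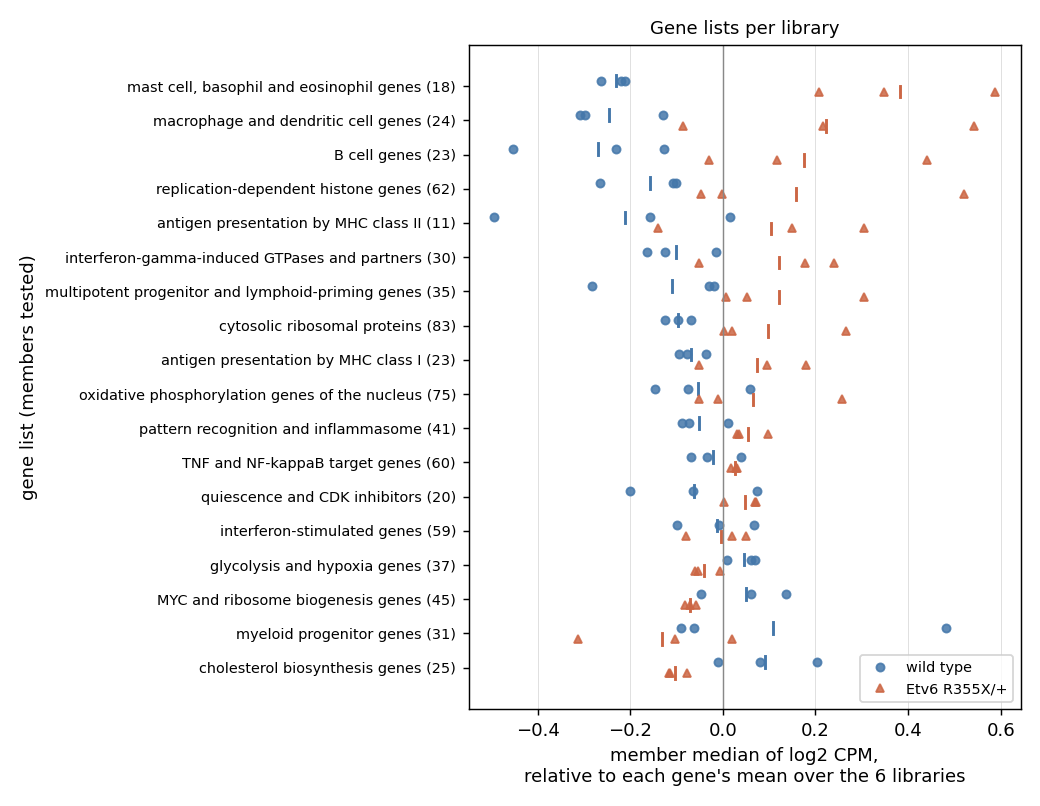
Median over each list's members of log2 CPM relative to each gene's mean over the 6 libraries, for the 16 lists that passed camera and the interferon-stimulated and TNF lists; circles are wild-type and triangles Etv6 R355X/+ libraries, ticks are genotype means, and member counts stand in brackets. Mast cell, basophil and eosinophil genes lead with a median log2 fold change of 0.59, and mutant replicate 1 lies far to the right in the ribosomal protein and histone lists.

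Cholesterol biosynthesis, MYC and glycolysis lists passed camera as lower in the mutant at the preset correlation. Cholesterol biosynthesis genes were below 0 in 22 of 25 members (median -0.23, camera adjusted p = 1.46e-07; adjusted p = 0.406 with an estimated correlation). Over all genes 1 member passed, and adjusted over the list alone 7 did, all lower. The feedback regulator Insig1 measured 31.0 ± 5.19 and 20.7 ± 0.844 CPM in wild type and mutant. The cholesterol median was -0.14 without wild-type replicate 2. Genes of the MYC and ribosome biogenesis list were below 0 in 38 of 45 (median -0.15, camera adjusted p = 3.00e-07; adjusted p = 0.501 with an estimated correlation), Myc itself at 301 ± 44.6 and 231 ± 11.0 CPM. In edgeR's quasi-likelihood test 0 of them passed over all genes or adjusted over the list alone and 17 had an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 0. The MYC median was -0.088 without mutant replicate 1 and wild-type replicate 3 together. Glycolysis and hypoxia genes were below 0 in 28 of 37 (median -0.083, camera adjusted p = 0.000348; adjusted p = 0.396 with an estimated correlation), and Ndrg1 alone passed, over all genes and adjusted over the list alone.

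Ribosomal protein genes were above 0 in 83 of 83 members (median 0.20, camera adjusted p = 3.18e-32; adjusted p = 0.406 with an estimated correlation), with Rpl39 at 519 ± 11.8 and 657 ± 85.2 CPM. Replication-dependent histone genes were above 0 in 59 of 62 (median 0.37, camera adjusted p = 9.07e-15; adjusted p = 0.406 with an estimated correlation), with Hist1h2ak at 45.8 ± 3.30 and 59.6 ± 7.98 CPM. Nuclear genes of oxidative phosphorylation were above 0 in 66 of 75 (median 0.11, camera adjusted p = 2.99e-07; adjusted p = 0.700 with an estimated correlation). In these 3 lists 0 members passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone. Unadjusted p lay under 0.05 for 59, 18 and 9 of them, DESeq2 called 3, 5 and 0, and limma-voom 0 in each. Without mutant replicate 1, the library richest in nuclear-encoded ribosomal RNA, the medians were 0.11, 0.15 and 0.012, and the oxidative phosphorylation call ended (adjusted p = 0.239). The oxidative phosphorylation median was 0.068 and 0.18 without wild-type replicate 1 and wild-type replicate 3, and 0.054 with the length and GC trend removed.

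Quiescence and CDK inhibitor genes were above 0 in 16 of 20 (median 0.058, camera adjusted p = 0.0309; adjusted p = 0.501 with an estimated correlation), with Txnip at 244 ± 66.1 and 332 ± 9.82 CPM. None passed edgeR's quasi-likelihood test over all genes, 0 adjusted over the list alone, and 5 had an unadjusted p under 0.05; DESeq2 and limma-voom called 0. The call ended without wild-type replicate 3 (adjusted p = 0.289) and without mutant replicate 2 (adjusted p = 0.0804). Without mutant replicate 1 and wild-type replicate 3 together the adjusted p was 0.278. Medians were 0.13 and 0.089 without wild-type replicate 1 and mutant replicate 3. Cell cycle lists did not pass, with medians of 0.039 for DNA replication (camera adjusted p = 0.122) and 0.011 for mitosis (camera adjusted p = 0.264), and adjusted p = 0.844 and 0.883 with an estimated correlation. In these 2 lists edgeR, DESeq2 and limma-voom called 0 genes, 0 passed adjusted over the list alone, and 1 and 0 had an unadjusted p under 0.05. Without wild-type replicate 3 both passed as higher (adjusted p = 0.000261 and 5.37e-12), as they did without mutant replicate 1 and wild-type replicate 3 together (adjusted p = 0.0352 and 2.39e-08). DNA replication also passed without mutant replicate 3 (adjusted p = 0.0221) and with the length and GC trend removed (adjusted p = 0.0200). Without wild-type replicate 1, wild-type replicate 2 and mutant replicate 1 the medians were 0.013, 0.012 and -0.0044 for DNA replication and -0.034, -0.055 and -0.033 for mitosis, and for mitosis 0.034 and 0.024 without mutant replicate 2 and mutant replicate 3. In all, 16 of 34 lists passed camera, 12 higher and 4 lower, and 0 held with an estimated correlation, where the smallest adjusted p was 0.396.

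The other lists that did not pass were those of the unfolded protein response (median -0.062, camera adjusted p = 0.0638), p53 targets (0.068, 0.156), megakaryocytes and platelets (-0.080, 0.166) and apoptosis regulators (0.045, 0.207). Mitochondrial genome genes (-0.090, 0.385), ETS factors (-0.0067, 0.448), hematopoietic transcription factors (-0.0054, 0.499) and endothelial and stromal genes (0.087, 0.549) did not pass. Cytokine receptor and JAK-STAT genes (0.00074, 0.681), immediate-early and cell-handling genes (-0.0024, 0.681) and mature neutrophil genes (-0.025, 0.767) did not pass either. With an estimated correlation the adjusted p of these 11 lists lay between 0.406 and 0.921. For immediate-early and neutrophil genes the mean was 0.17 and 0.25, opposite in sign to the median, and the camera direction followed the mean. Over all genes the cochaperone gene Dnajb1 of the immediate-early and cell-handling list (log2 fold change 0.38, SE 0.064) and Stfa1 of the neutrophil list passed, and adjusted over the list alone 6 and 1 did. The heat-shock genes Hspa1a and Hspa1b of the cell-handling list measured 2.10 ± 0.858 and 2.64 ± 1.21 CPM in wild type and 11.5 ± 8.40 and 11.7 ± 8.16 CPM in the mutant, without overlap, and did not pass over all genes (log2 fold change 2.46 and 2.15). The neutrophil gene Chil3 measured 224 ± 15.3 and 175 ± 39.1 CPM in wild type and mutant. In the first 9 lists, in the order given, edgeR's quasi-likelihood test called 0 genes over all genes, and 5, 3, 6, 2, 0, 4, 5, 6 and 8 had an unadjusted p under 0.05. Adjusted over the list alone 0, 1, 3, 0, 0, 2, 1, 3 and 0 passed, DESeq2 called 0, 1, 3, 0, 0, 0, 1, 2 and 1, and limma-voom 1 of the megakaryocyte genes.

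The medians of these 11 lists moved with the libraries. For the unfolded protein response they were -0.10, -0.0088, -0.11 and -0.011 without wild-type replicate 1, wild-type replicate 3, mutant replicate 2 and mutant replicate 3, and for p53 targets 0.037 and 0.033 without mutant replicate 1 and mutant replicate 2. Megakaryocyte genes stood at -0.020 and -0.041 without wild-type replicate 3 and mutant replicate 3, apoptosis regulators at 0.029 without mutant replicate 3, and mitochondrial genome genes at -0.042, -0.046 and -0.048 without wild-type replicate 1, wild-type replicate 3 and mutant replicate 2. Endothelial and stromal genes changed sign without wild-type replicate 2, wild-type replicate 3 and mutant replicate 3 (medians -0.29, -0.093 and -0.20). They stood at 0.17 and 0.0019 without wild-type replicate 1 and mutant replicate 2, and passed fry's mixed test (adjusted p = 0.00794). When single libraries were left out, medians ran from -0.055 (mutant replicate 3) to 0.020 (wild-type replicate 1) for ETS factors and from -0.026 (mutant replicate 2) to 0.00019 (mutant replicate 1) for hematopoietic transcription factors. They ran from -0.0032 (wild-type replicate 1) to 0.028 (wild-type replicate 2) for cytokine receptors and from -0.040 (wild-type replicate 3) to 0.099 (wild-type replicate 1) for immediate-early genes.

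Some of these lists passed in another setting. Unfolded protein response genes were lower without wild-type replicate 1, mutant replicate 1 and mutant replicate 2 (adjusted p = 0.000375, 0.0385 and 0.00229), with library size alone (adjusted p = 0.0299) and with a filter of 1 CPM in 3 libraries. Megakaryocyte genes were lower without wild-type replicate 1 and mutant replicate 2 (adjusted p = 0.0313 and 0.0357), and mitochondrial genome genes without wild-type replicate 2 and mutant replicate 1 (adjusted p = 0.0130 and 0.00102). The latter also passed as lower without mutant replicate 1 and wild-type replicate 3 together (adjusted p = 0.0172) and with the length and GC trend removed (adjusted p = 0.0420). Neutrophil genes were lower without mutant replicate 1 (median -0.15, adjusted p = 0.0210) and higher without mutant replicate 3 (median 0.097, adjusted p = 0.0338).

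Neither sorting marker was among the 55 genes that passed, and both had a lower mean in the mutant. Kit measured 419 ± 33.0 CPM in wild type and 378 ± 23.5 CPM in the mutant, and Ly6a, which encodes Sca-1, 85.8 ± 12.2 and 78.2 ± 2.80 CPM. All libraries expressed Y-linked genes, with Kdm5d at 76.3 ± 4.35 and 81.1 ± 2.14 CPM, and Xist stood at 4.02 ± 1.42 and 3.19 ± 0.874 CPM.

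**Figure D3:**
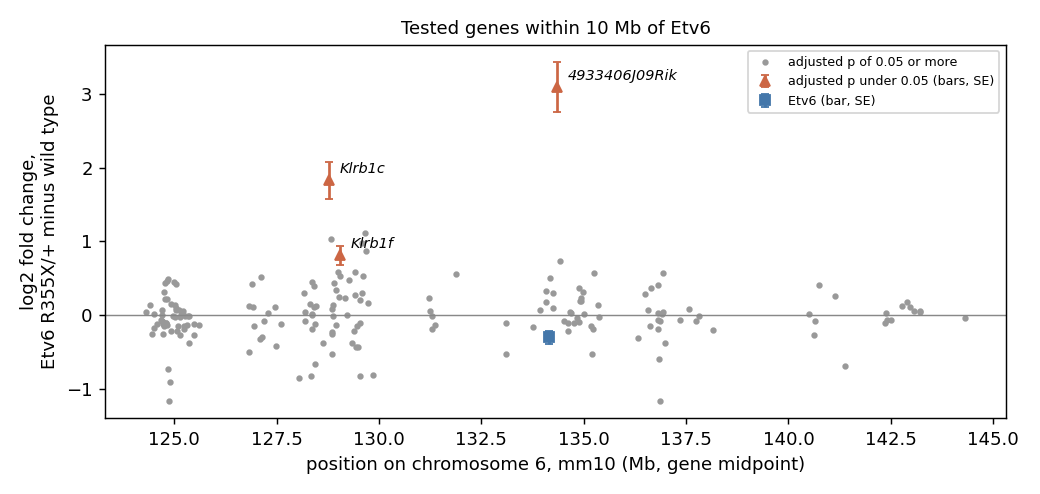
Log2 fold change of Etv6 R355X/+ minus wild type for the tested genes within 10 Mb of Etv6 on chromosome 6 (mm10, position in Mb on the horizontal axis); triangles passed the adjusted threshold, the square is Etv6, and bars are SE. Etv6 lies at -0.30, and the 3 genes that passed, Klrb1c, Klrb1f and 4933406J09Rik (the last 2 named here after their values were seen), lie at 1.82, 0.81 and 3.10.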

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

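Of these settings, the trend with length and GC content, the removal of ribosomal RNA genes and the joint removal of mutant replicate 1 and wild-type replicate 3 were chosen after seeing the data. All 55 genes kept their sign in every setting that tested them, and RLE factors, unrounded counts and the removal of mitochondrial or ribosomal RNA genes left the same 55. DESeq2 called 329 genes (208 higher, 121 lower, 54 shared), and the fit without a count filter called 527 (336 higher, 191 lower, all 55 shared), of which 30 were not tested in the filtered fit; the cause of the rest was not tested. Robust estimation called 81 genes with 59 higher, limma-voom 41, library size alone 59, a filter of 1 CPM in 3 libraries 53 and the trend correction 68. The test against a fold of 1.2 called 23 (18 higher, 5 lower), as a stricter null does by construction. Deviations of same-numbered libraries correlated at -0.020, -0.025 and -0.085. This gives no sign of pairing by replicate number across all genes, but cannot exclude a pairing that touches few genes. The fit with the replicate number as a block called 32 genes (27 higher, 5 lower, 26 shared). Leaving out one library at a time, with fewer samples, gave 16 to 67 genes (13 to 57 higher, 2 to 21 lower). Without mutant replicate 1 and wild-type replicate 3 there were 33 higher and 23 lower. Etv6 expression stayed lower in the mutant throughout and passed only without a count filter (-0.30, adjusted p = 0.0111; adjusted p elsewhere 0.0537 to 1.00); the cause was not tested. With an estimated correlation 0 lists passed and with fry 0, whose smallest adjusted p was 0.0949; fry's mixed test passed 6. Lists passing camera in every fit that left out a library numbered 13 of 16. The median of the interferon-stimulated list ranged from -0.025 to 0.062 when a library was left out and was -0.051 without mutant replicate 1 and wild-type replicate 3; that of the TNF and NF-kappaB list ranged from 0.038 to 0.092. For mature neutrophil genes, with a median of -0.025 but a camera direction of higher (adjusted p = 0.767), camera passed as lower without mutant replicate 1 (-0.15) and without it and wild-type replicate 3 (-0.21), passed as higher without mutant replicate 3 (0.097), and pointed lower without passing when wild-type replicate 2 or 3 was left out or the trend removed. Erythroid genes reversed without wild-type replicate 3 (0.25), against -0.37 without wild-type replicate 1; the cause was not tested. Depth limits low genes most: Igkv3-4 rests on 7 wild-type and 690 mutant counts, and Stfa1 on 13 and 594.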

Other observations

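The genes in this paragraph outside the naming rule were chosen after their values were seen. Called genes outside the fixed lists included Ccm2l, which rose from 5.88 ± 0.139 to 14.4 ± 2.45 CPM, She, from 0.764 ± 0.114 to 2.21 ± 0.238 CPM, and Egfl7, from 32.8 ± 2.63 to 46.3 ± 2.65 CPM (SD, n = 3). Their adjusted p was 0.00522, 0.0371 and 0.0390 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These 3 genes were not tested as a group. The fixed list of endothelial and stromal genes did not pass camera (median 0.087, 10 of 19 above 0, adjusted p = 0.549) but passed fry's mixed test (adjusted p = 0.00794), its median changed sign without wild-type replicate 2, wild-type replicate 3 or mutant replicate 3 (-0.29, -0.093 and -0.20), and its member Emcn was lower without overlap at 12.4 ± 2.07 and 9.13 ± 0.955 CPM in wild type and mutant (log2 fold change -0.45, unadjusted p = 0.0136 in edgeR's quasi-likelihood test). While both adult beta-globin genes rose, the alpha-globin genes Hba-a1 and Hba-a2 measured 7.14 ± 2.05 and 3.25 ± 1.21 CPM in wild type and 7.22 ± 3.62 and 3.35 ± 2.14 CPM in the mutant. The erythroid regulator Klf1 measured 7.14 ± 5.64 and 5.84 ± 2.03 CPM. The miRNA gene Gm24187 had 269 counts over the 3 wild-type libraries and 2 over the 3 mutant libraries.

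Chosen after the result was seen were the tests without mutant replicate 1, the removal of the trend with length and GC content, all tests of early B-lineage genes and of the B cell list, and both tests of the number of calls near Etv6. With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The real split called 55 genes and the highest other 1, so 1 of the 10 splits gave as many. For the 39 higher genes the highest other was 1 and for the 16 lower genes 0, again 1 of 10 splits. For gene lists 4 of the 10 splits passed as many as the real 16. The other splits passed 10 to 22 lists, so a camera call at the preset correlation does not by itself separate the genotypes. For the interferon-stimulated list 7 of 10 splits had a camera p as small as the real 0.382 (smallest other 1.38e-08), and for the TNF and NF-kappaB list 4 of 10 as small as 0.163 (smallest other 0.0136).

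The first pattern is the joint rise of ribosomal protein and histone genes. Without mutant replicate 1 the difference of library medians was 0.106 (SE 0.016) for ribosomal proteins, against 0.194 (SE 0.087) with it. This argues against that library as the whole source for ribosomal proteins. For histones it was 0.138 (SE 0.060), against 0.315 (SE 0.190). The first value lay above 2 SE and the second under 2 SE, with few libraries left, so for histones this test cannot decide. With the trend of length and GC content removed, the differences were 0.128 (SE 0.071) and 0.228 (SE 0.148), both under 2 SE, the outcome set for the trend as cause after the data, but before these 2 values, were seen. Both fell by less than their SE, and histones lay under 2 SE before the correction too, so a trend and a change in these genes cannot be told apart here; the requirement that the trend take away most of the difference was added after the values were seen. The genotype itself stays among the open explanations, untested.

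The second pattern is the early B-lineage set Rag1, Rag2, Dntt, Vpreb1, Vpreb3, Igll1, Ebf1, Pax5, Cd79a and Blnk, put together after their values were seen, of which 10 of 10 were above 0 and 9 had an unadjusted p under 0.05, but 0 passed edgeR's quasi-likelihood test after adjustment. Of these 10 genes, 4 are in the B cell list and 6 in the multipotent progenitor and lymphoid-priming list. The rises of this set and of those lists are therefore not separate findings. Library medians of the early B-lineage set were 0.956 (SE 0.367) higher in the mutant and 0.614 (SE 0.263) higher without mutant replicate 1. They exceeded mature B and plasma cell genes by 0.867 (SE 0.322) and mature neutrophil genes by 0.968 (SE 0.233). Of the 16 mature B and plasma cell genes 11 were above 0, but Igha and Ighg1 were lower without overlap (log2 fold change -1.08 and -2.33). The first excess is therefore not over a uniform set. Picking genes that had risen builds in such an excess, and Igkc and Ighm, at 1713 ± 452 and 1688 ± 427 CPM in wild type, would hide a small added share, so carried-over B-lineage cells, fewer LSK cells, mutant replicate 1 alone and a change in these transcripts cannot be told apart for this set. The B cell list, fixed before the data were examined, was 0.345 (SE 0.135) higher without mutant replicate 1, which argues against that library alone, and exceeded the mature neutrophil list by 0.458 (SE 0.098), but neutrophil members went both ways (10 of 20 above 0) with a median wild-type level of 15.8 CPM against 12.8 CPM for B cell genes, so for that list too fewer LSK cells and other sources cannot be told apart. Library medians of the mast cell, basophil and eosinophil list (0.613, SE 0.112) and of the macrophage and dendritic cell list (0.469, SE 0.190) were higher in the mutant too, so a rise in several cell types stays open.

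The third pattern is the neighbourhood of Etv6, where 3 of 193 tested genes within 10 Mb passed against 0.515 expected (exact one-sided hypergeometric p = 0.0148). Chromosome 6 as a whole held 8 calls against 3.12 expected (exact one-sided hypergeometric p = 0.0119), 3 of them Igkv segments, while Klrb1c and Klrb1f are related neighbours and counted as 1 gene give p = 0.0902 for the 10 Mb in the same test, so chance placement and a local excess cannot be told apart with so few genes. The share of neighbours with an unadjusted p under 0.05 was 12.4% against 10.6% elsewhere (exact one-sided Fisher p = 0.237), which leaves a broad local effect undecided. The closest call, the lncRNA gene 4933406J09Rik on chromosome 6 from 134308951 to 134403415 (mm10, minus strand), has its near (3') end 38.8 kb beyond Etv6 with 0 annotated genes between and had 40 counts over the wild-type and 371 over the mutant libraries. It overlaps Bcl2l14 on the other strand over 7098 bases, and unstranded counts share such reads; Bcl2l14 had a log2 fold change of 0.73 (SE 0.25, adjusted p = 0.354 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).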
